A study of Caenorhabditis elegans with 4 samples.

How the data were processed

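Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Caenorhabditis elegans hermaphrodites at the first larval stage (L1). The animals, strain OP228, carried a transgene for NHR-237, a member of the nuclear hormone receptor family of transcription factors, fused to green fluorescent protein and a FLAG tag. Per the labels, the transgene was made by recombineering and introduced by bombardment into an unc-119 mutant. Per the labels' protocols, worms were grown at 20 °C on E. coli, crosslinked with 2% formaldehyde and sonicated. The tagged factor and its DNA were then collected with anti-GFP antibodies, and 10% of the lysate was kept as input. The stage label also carries the number 26, whose meaning is not given in the sources used here. The series holds 4 samples, 2 ChIP libraries and 2 input libraries, numbered 1 and 2 in the titles. Nothing says whether the replicates came from separate cultures, so the agreement between them may be technical.

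The files used were 3 peak lists, one per ChIP library and one combined list. The input libraries were not analysed here. Per the file headers, coordinates are in WormBase WS220, and the source column names the method as spp_via_IDR, that is, the SPP peak caller followed by the irreproducible discovery rate (IDR). The aligner, the read filters, the handling of input, and the SPP and IDR settings are not given in the sources used here. Each list has 1 deposited score per peak, from the authors' caller, whose meaning is not named in the file. Per the values, 10 to the power of minus the highest score equals 1 over 1037, 789 and 815 in the combined, replicate 1 and replicate 2 lists, as a −log10 false discovery rate would. Many peaks share the highest score, namely 519, 395 and 408 in the same order. The deposited files also number the peaks from 1. The number follows the score closely (Spearman's rho across peaks −0.94 in the combined list and −1.00 in both others) and was used to rank tied peaks. Other deposited values are the start and end of each peak, counted from 1. Read depth is not given in these lists, so it is unknown here, and the intervals below cover the counting of peaks only.

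The combined list was taken as the main list. Peaks of separate lists were called shared when they overlapped by at least 1 bp (bedtools 2.31.1). Chance overlap came from 1000 circular shifts of one list along each chromosome, with a one-sided p whose smallest value is 0.001. Shared peaks were ranked against each other with Spearman's rho and Pearson's r, each with 100000 permutations, over pairs that were each other's nearest peak. Chromosome lengths were taken as the largest peak end in any list, since the genome sequence of this build was not used here. Peaks per chromosome were tested with two-sided exact binomial tests against chromosome length, adjusted by Benjamini-Hochberg over 6 chromosomes, and with 100000 multinomial draws. The central part of a chromosome was the stretch from 25% to 75% of its length. Spacing was compared with 1000 uniform random placements. Shares carry 95% Wilson intervals. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.

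The methods were tested on simulated data. With 30% of 16621 simulated peaks placed on replicate 2 peaks, the overlap corrected for the share under shifts came to 30.2%. The overlaps in the Results are not corrected in this way, so they are not estimates of the truly shared part. Of 100 unrelated lists of 2000 peaks, 5 were called at 0.05. For 1119 simulated peaks, a 1.3-fold higher density on X was called in 93.3% of 1000 draws, and an equal density in 4.1%. These draws placed peaks independently, whereas the real peaks lay closer together than random, so the rates may not hold for the real lists.

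The peak lists use WS220, and the only gene table at hand belongs to another assembly (WBcel235). Coordinates of one build were not applied to the other, so the planned analyses of genes near peaks, gene lists, the transgene loci and short sequences were not run. Peaks are therefore named by position. The rule fixed before the data were examined took the 10 combined peaks with the highest score, in genomic order where tied. Because of the 519 ties, the 25 combined peaks with the lowest numbers are reported as well, a choice made after the data were seen. The comparisons by rank, by 1 Mb and 0.5 Mb windows with shifts of 5 to 50 kb, of the central share of the autosomes with that of X, and of the latter between lists were also added then. The alternatives tried were a reciprocal overlap of 50%, peak centres within 200 bp, shorter lists by score or number, merging of peaks within 2 kb, other placements, and each replicate alone. A planned permutation test found different median scores (0.081 and 0.060, p = 1e-05) and widths (420 and 456 bp, p = 1e-05) in the replicate lists, the smallest p that 100000 permutations give. Both values were set separately for each library, so they were not read as a difference in binding.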

Results

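The data list sites of the C. elegans genome called as enriched after ChIP of the tagged nuclear hormone receptor NHR-237 in L1 larvae. The series holds no untagged control and the inputs were not analysed here. Sites enriched for reasons other than NHR-237 binding were therefore not separated. The combined list held 1119 peaks, the list of ChIP replicate 1 held 16621 and that of replicate 2 held 18457. Nearly every peak of a list had the same width, 450 bp in the combined list, 420 bp in replicate 1 and 456 bp in replicate 2. Narrower peaks numbered 49, 25 and 13 in the same order, and none had a peak number above 189, 167 and 79, with number 1 taken as the strongest peak. Combined peaks covered 0.487 Mb, or 0.486% of the genome, against 6.76% for replicate 1 and 8.03% for replicate 2. Scores had a median of 2.65 in the combined list (range 1.36 to 3.02), 0.081 in replicate 1 and 0.060 in replicate 2. There were 2 ChIP libraries and no other group with a peak list, so the comparisons are between replicates, between lists and between parts of the genome. All coordinates are WormBase WS220, and the gene, exon or UTR at each site was not analysed here.

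The strongest combined peaks had high ranks in both replicates. The combined list was made from the same 2 libraries by the method named spp_via_IDR, whose settings are not given in the sources used here. Part of this agreement may therefore follow from how its sites were chosen. Combined peak 1 lay on chromosome III from 3867431 to 3867691 and was peak 3 of replicate 1 and peak 1 of replicate 2. Combined peak 2, on chromosome II from 10563403 to 10563631, was peak 2 and peak 3 of the replicates. Combined peak 3 lay on X from 9465710 to 9465861 and was peak 9 and peak 2. Combined peak 4, on chromosome III from 10758988 to 10759264, was peak 5 and peak 10. Combined peak 5, on chromosome II from 8561286 to 8561482, was peak 4 and peak 11. Combined peak 6, on chromosome IV from 4749937 to 4750188, was peak 7 and peak 4. Combined peak 7, on X from 5841169 to 5841390, was peak 1 and peak 25.

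The 25 combined peaks with the lowest numbers ranked no lower than 67 in replicate 1 and 31 in replicate 2. Their centres lay within 42.5 bp of the replicate 1 centre and 49.5 bp of the replicate 2 centre. Of these 25 peaks, 10 were on X, 8 on chromosome III, 3 each on II and IV, 1 on I and 0 on V. All but 1 were narrower than 450 bp, and the narrowest (peak 14, chromosome II, 5844693 to 5844806) spanned 114 bp. Further X sites among them were at 4209102 to 4209368, 2996992 to 2997170, 16681953 to 16682130 and 12363018 to 12363177. Further chromosome III sites were at 5678998 to 5679193, 7854518 to 7854743, 12612359 to 12612808 and 6971936 to 6972168. The site on chromosome I was at 4172039 to 4172234.

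The rule fixed before the data were examined named 10 peaks that share the highest score, and all lay on the left end of chromosome I between 16779 and 1070189. Their replicate numbers were close for some and far apart for others. The peak at 315011 to 315460 was number 61 in replicate 1 and 96 in replicate 2, and that at 535369 to 535563 was number 69 and 43. The peak at 26970 to 27419 was number 505 in replicate 1 and 313 in replicate 2. The peak at 1069740 to 1070189 was number 2102 in replicate 1 and 130 in replicate 2. The peak at 1068058 to 1068507 went the other way, with number 274 in replicate 1 and 1527 in replicate 2. Both belong to a run of 3 peaks from 1066939 to 1070189.

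Whether peaks repeated between the replicates was asked of the full lists. Of the replicate 1 peaks, 6449 of 16621 (38.8%, interval 38.1 to 39.5) overlapped a replicate 2 peak. In the other direction, 6690 of 18457 (36.2%, interval 35.6 to 36.9) did. Shifted lists overlapped by 15% ± 0.296 (SD of 1000 shifts) and 13.7% ± 0.268. The observed overlap was 2.59 and 2.64 times as high, and no shift reached it (permutation p = 0.001 in both directions, one-sided, the smallest possible).

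Repeatability fell steadily with rank. Among peaks 1 to 500, 98% of replicate 1 (interval 96.4 to 98.9) and 98.6% of replicate 2 (97.1 to 99.3) overlapped the other library. For peaks 1001 to 2000 these shares were 69.3% and 62.9%, and for peaks 4001 to 8000 they were 34.1% and 34.9%. Among the lowest-ranked peaks, from 12001 on, 27.1% of replicate 1 (interval 25.8 to 28.4) and 24.9% of replicate 2 (23.8 to 26.0) still overlapped, against 15% and 13.8% by chance.

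**Figure D1:**
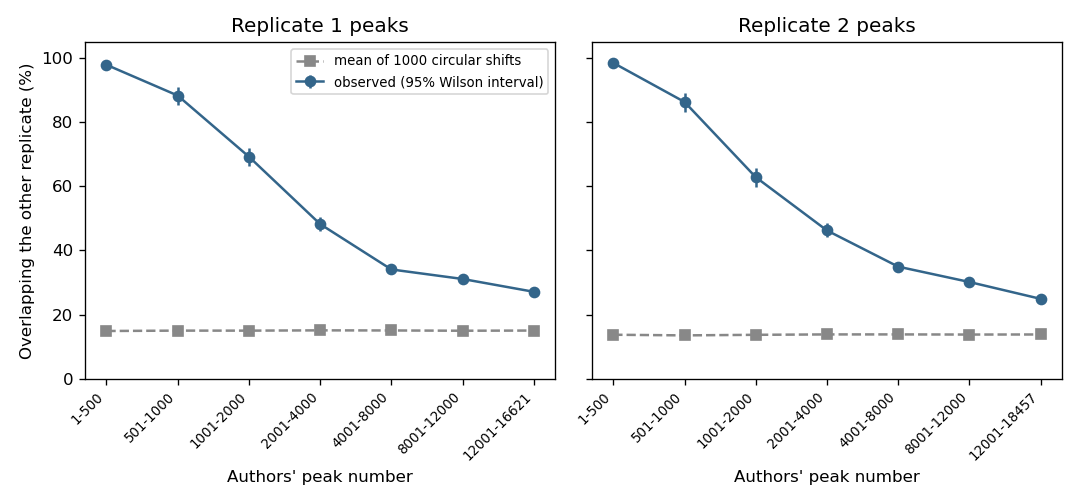
The share of peaks of each replicate (y axis, percent) that overlapped a peak of the other replicate, by the authors' peak number (x axis), with 95% Wilson intervals, and the mean share under 1000 circular shifts (squares). The share falls from 98% and 98.6% in the first class to 27.1% and 24.9% in the last, above the chance level throughout.

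Shared sites had correlated strengths. Over 5985 shared peaks, the scores of the replicates gave a Spearman's rho of 0.46 and a Pearson's r of 0.68 (permutation p = 1e-05 each, the smallest possible). These are correlations across peaks, which are not independent replicates. Peak centres differed by a median of 61 bp (quartiles 24 and 146 bp), with a median signed difference of 0 bp. The required overlap by itself keeps centres close, and no chance value of this distance was computed.

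The combined list was asked which replicate sites it contains. Of its 1119 peaks, 1117 (99.8%) overlapped a replicate 1 peak and 1110 (99.2%) a replicate 2 peak, and 1108 (99%, interval 98.2 to 99.5) overlapped both. The list was made from these same 2 libraries, so such high shares may follow from its making and are no independent check. No combined interval was identical to a replicate interval. Centres lay a median of 14 bp from the replicate 1 centre and 9.25 bp from the replicate 2 centre. The 11 combined peaks without a peak in one replicate included chromosome II 9273960 to 9274409 (number 642, replicate 1 only) and chromosome IV 12558955 to 12559404 (number 962, replicate 2 only). The matching peaks had a median number of 554 in replicate 1 and 568.5 in replicate 2, taking the best-ranked peak where several overlapped. Of each replicate's own top 1119 peaks, 900 (80.4%) of replicate 1 and 835 (74.6%) of replicate 2 were in the combined list. Under the top 1000 peaks of each replicate alone, 55% of combined peaks were matched in both.

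Combined peaks were spread unevenly over the chromosomes. Chromosome III carried the most per length, with 193 peaks or 14 per Mb, 1.25 times the 154 expected (adjusted p = 0.0029, exact binomial). Chromosome V carried the fewest, with 173 peaks or 8.27 per Mb, 0.741 times the 234 expected (adjusted p = 2.9e-05, exact binomial). Chromosomes I (191 peaks, 12.7 per Mb, adjusted p = 0.12), II (178, 11.7 per Mb, 0.80) and IV (192, 11 per Mb, 0.84) did not pass the exact test. Over the 6 chromosomes the counts differed from those expected by length (p = 3e-05, exact multinomial null sampled with 100000 draws). These tests treat peaks as independent, and the chromosome III ratio was 0.983 and 1.0 in the full replicate lists. By rank, its share was 23% of replicate 1 and 21% of replicate 2 peaks among peaks 1 to 100, and 13% and 13.3% among peaks 5001 to 10000, against 13.7% of the length.

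X carried 192 combined peaks, 10.8 per Mb against 11.2 per Mb on the autosomes, a ratio of 0.965 that did not pass the test (exact binomial p = 0.70). The full replicate lists differed from this, but they are far longer and reach much lower scores, with medians of 0.081 and 0.060. If the score is a −log10 false discovery rate, which no source states, many of these calls would be false. Only 1365 peaks of replicate 1 and 823 of replicate 2 scored at least 1.36, the lowest combined score. The exact tests below also treat peaks as independent. X held 21.6% of replicate 1 peaks and 19.7% of replicate 2 peaks, against 17.7% of the length, and the density ratios to the autosomes were 1.29 (exact binomial p = 4.8e-39) and 1.14 (p = 2e-12). By rank, the X share was highest among the first 100 peaks of each list, but a random order of X and other combined peaks was not excluded (permutation, adjusted p = 0.074). Of the 100 strongest combined peaks 27 were on X (interval 19.3 to 36.4%), and of the same class 27 in replicate 1 and 30 in replicate 2. Among peaks 301 to 600, 13.7% of combined peaks (interval 10.2 to 18), 20% of replicate 1 peaks and 13% of replicate 2 peaks were on X. Replicate 1 stayed between 18% and 22.3% in all classes below the first 100.

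**Figure D2:**
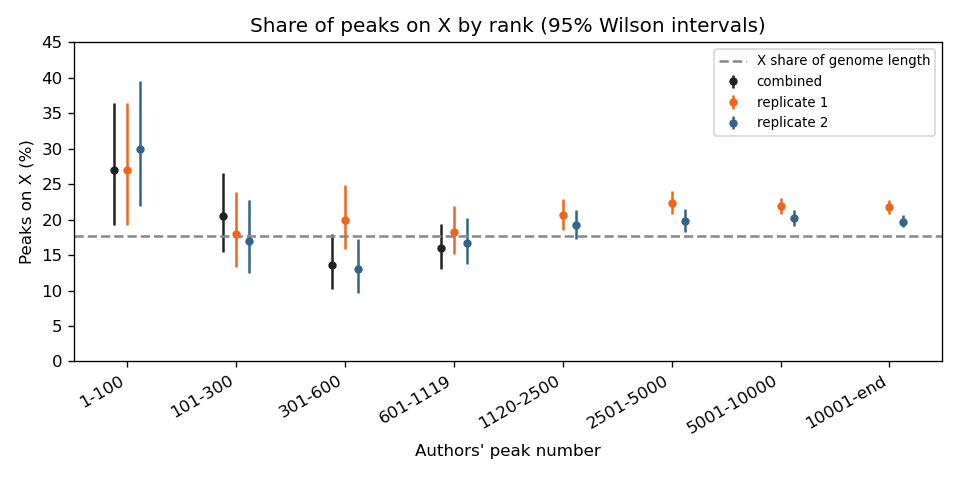
The share of peaks on X (y axis, percent, with 95% Wilson intervals) by the authors' peak number (x axis) in the 3 lists, with the X share of genome length (17.7%) as a dashed line. The share is 27% to 30% for peaks 1 to 100, and for peaks 301 to 600 it is 13.7% in the combined list, 20% in replicate 1 and 13% in replicate 2.

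Autosomal combined peaks favoured chromosome centres. Of 927 autosomal combined peaks, 560 (60.4%, interval 57.2 to 63.5) lay in the central part, where 50% would be expected by length alone (exact binomial p = 2.5e-10). The share was highest on chromosome V, at 67.6% (exact binomial, adjusted p = 2.4e-05). By the same exact test it was 61.8% on II (adjusted p = 0.0061) and 60.7% on I (adjusted p = 0.0074). Chromosomes III (56.0%, adjusted p = 0.14) and IV (56.8%, adjusted p = 0.11) did not pass the exact test. On X, 46.4% of peaks were central (interval 39.4 to 53.4, exact binomial, adjusted p = 0.35). In a comparison added after the data were seen, the autosomal and X shares differed (odds ratio 1.77, Fisher's exact p = 0.0004). In the full replicate lists the X share was 53.1% and 50.2%, and the odds ratios were smaller, at 1.31 (Fisher's exact p = 8.7e-13) and 1.26 (p = 9.2e-10). Weak autosomal calls were also central more often than length gives. In the lowest-ranked class of peaks the central share was 57.5% in replicate 1 and 52.6% in replicate 2. The preference for centres is therefore not specific to the selected sites. Whether it follows from other differences along the chromosomes, such as gene content, was not tested.

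In 1 Mb windows the combined list had a median of 10 peaks and a range of 2 to 26 over 97 full windows. The densest window was chromosome I from 9 to 10 Mb with 26 peaks, more than the densest window of most random placements (permutation p = 0.030, 10000 placements, one-sided). These placements were uniform and independent along each chromosome. The real peaks favoured the centre of chromosome I, where this window lies, and lay closer together than random. The p-values of the windows may therefore be too small. Chromosome III from 8 to 9 Mb followed with 25 peaks (permutation p = 0.066) and chromosome II from 5 to 6 Mb with 22 (p = 0.44). The emptiest was chromosome II from 2 to 3 Mb with 2 peaks (permutation p = 0.22).

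**Figure D3:**
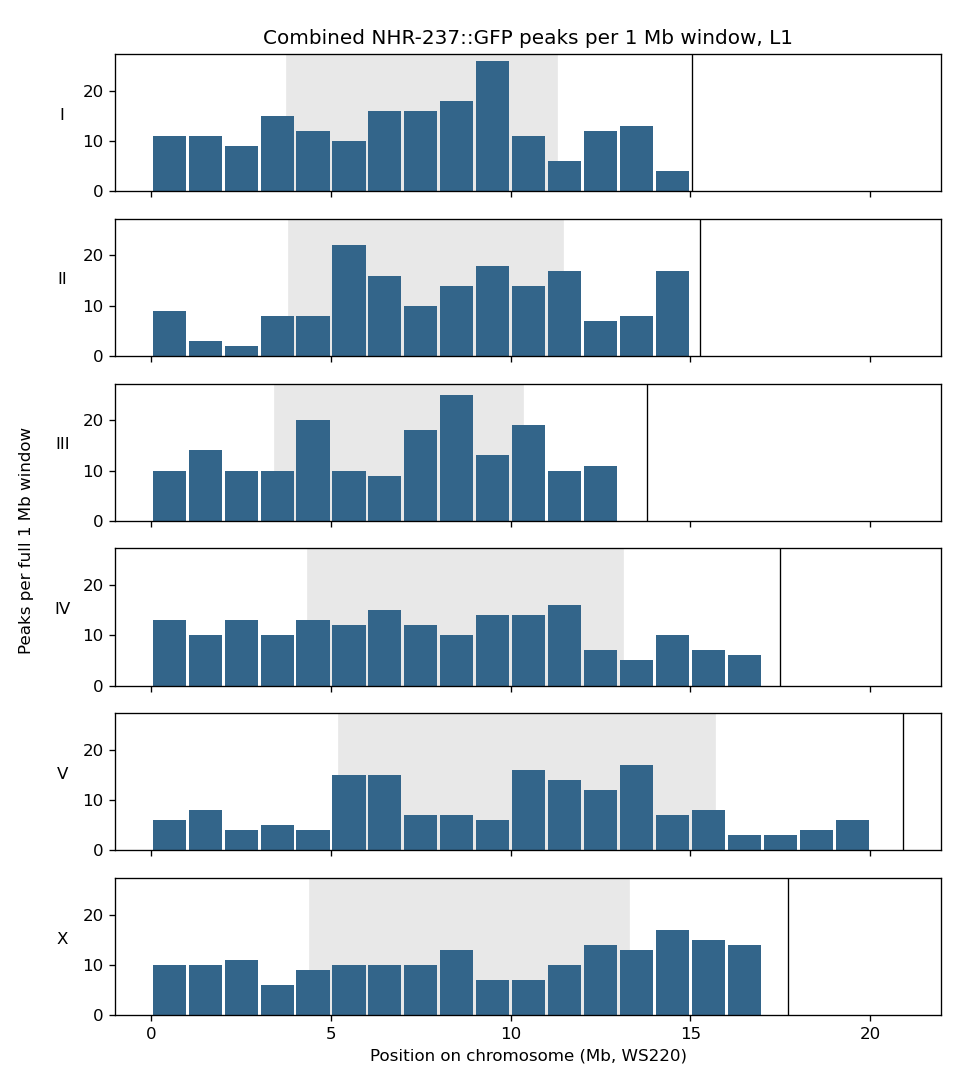
Combined peaks per full 1 Mb window (y axis) along each chromosome (x axis, Mb, WS220), with the central part of the length shaded and the chromosome end as a line. Chromosome I from 9 to 10 Mb reaches 26 peaks, chromosome V has low counts outside its shaded centre, and X shows no such rise in its centre.

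Sites also lay closer together than random placement gives. The median distance to the nearest other combined peak was 22.9 kb, against 30.7 kb ± 1.52 (SD of 1000 placements), 0.746 times as far (permutation p = 0.001, one-sided, the smallest possible). A neighbour within 2 kb was found for 124 peaks, against 49.9 ± 9.39 in random placements. In the combined list 16 pairs of adjacent peaks overlapped each other, so some of these neighbours may not be separate sites. Merging such neighbours left 1052 regions, of which 57 held 2 or more peaks and 10 held 3. Regions of 3 included X 16929424 to 16931111, whose best peak was number 41, chromosome III 8794669 to 8797502 (number 100) and chromosome II 5660857 to 5662216 (number 149).

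The replicate lists differed in where their peaks lay on chromosome IV. From 13500001 to the end of that chromosome, replicate 2 listed 1023 peaks (5.54% of its list, interval 5.22 to 5.88) and replicate 1 listed 625 (3.76%, interval 3.48 to 4.06), while the region is 3.98% of the length. The ratio of replicate 2 to replicate 1 peaks there was 1.64, against 1.09 elsewhere, a ratio of ratios of 1.50 (95% interval 1.36 to 1.66, which covers the counting of peaks). The combined list had 29 peaks in this region. The comparison is between 2 libraries of the same group, and the region was chosen after its values were seen.

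**Figure D4:**
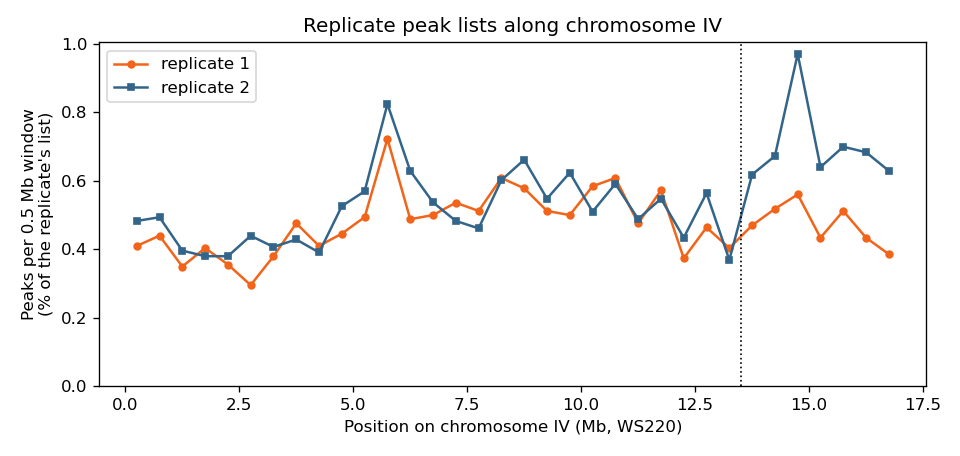
Peaks per full 0.5 Mb window along chromosome IV (x axis, Mb, WS220) as a percent of each replicate's list (y axis). Beyond the dotted line at 13.5 Mb replicate 2 lies above replicate 1 in every window, and before it the order varies, with replicate 2 also well above from 2.5 to 3 Mb (81 peaks against 49). Beyond the line the lists hold 5.54% of replicate 2 and 3.76% of replicate 1 peaks.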

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

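Of 46 alternatives to 11 results, 35 kept the direction and the side of the threshold, or stayed within the interval of a share that had no test. The replicate overlap stayed above chance under all 6 alternatives in each direction, from 28.2% to 61.8%, and Spearman's rho ran from 0.46 to 0.56. The central autosomal share stayed between 55.9% and 60.3%, and the odds ratio of autosomal to X central shares, a test added after the data were seen, between 1.26 and 2.07. The single replicate lists gave central autosomal shares of 59.8% and 55.9%. Most of their peaks scored below the lowest combined score, so these shares are no check on the selected sites. The X central share of 46.4%, which passed no test, turned to 53.1% in replicate 1 alone (exact binomial p = 0.0002) and 50.2% in replicate 2 alone (exact binomial p = 0.78). The spacing ratio stayed between 0.756 and 0.770. The share of combined peaks found in both replicates moved to 95.4% with a reciprocal overlap of 50%, to 100% for the upper part of the combined list by score, and to 55% against the top 1000 peaks of each replicate. With one replicate left out, which can only raise the share, it was 99.2% to 99.8%. The X to autosome ratio, which passed no test in the combined list, turned to 1.05 (exact binomial p = 0.66) for the upper part of that list by score. In the lists of the single replicates it was 1.14 to 1.29, past the threshold, but most of their peaks scored below the lowest combined score of 1.36. The chromosome III ratio of 1.25 was 0.983 to 1.0 in the single replicate lists and passed no test there. Its share was 23% and 21% among peaks 1 to 100 of the replicate lists and 13% and 13.3% among peaks 5001 to 10000, so the many low-ranked peaks lower the ratio of the full lists. The low chromosome V ratio passed in every list, at 0.669 to 0.924. No paired analysis was possible because the input libraries, which share the replicate numbers of the ChIP libraries, were not analysed here. Variations of the analyses of genes near peaks, gene lists and short sequences were planned but not run, for want of an annotation of this build. Read depth is unknown, so a site missing from one replicate list is not shown to be unbound.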

Other observations

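The tests on chromosome IV with equal list lengths and with ranks, and the test of merged peaks on chromosome III, were fixed before their results were seen; all other tests here were chosen after the pattern had been seen.

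The chromosome shares of the 300 strongest combined peaks were compared with those of the rest, at a boundary picked by eye. Among the 300 strongest combined peaks, 66 (22%, interval 17.7 to 27) were on chromosome III, against 127 of the other 819 (15.5%; Fisher's exact adjusted p = 0.025). By the same exact test X held 68 (22.7%) against 15.1% (adjusted p = 0.025), and chromosome V held 33 (11%) against 17.1% (adjusted p = 0.025). Chromosomes I, II and IV did not pass, at adjusted p of 0.65, 0.096 and 0.091. On X, 10 of the 27 peaks in the top 100 were in the central part, and 44 of 83 (53.0%) among combined peaks 601 to 1119.

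To avoid that boundary, the running excess over the whole ranking was tested by permutation, adjusted over 6 chromosomes. Chromosome III passed (permutation, adjusted p = 0.014), with 103 of the first 463 peaks (22.2%). X (permutation, adjusted p = 0.074) and chromosome V (0.074) did not, so a random order remains open for these. For chromosome III, counting close neighbours more than once was argued against, since the adjusted p was 0.011 after merging within 2 kb. No chromosome-wide excess of peak calls was seen in the full replicate lists. There the share of chromosome III was at most 13.8%, against 13.7% of the length. Most of those peaks scored below the lowest combined score, so this cannot decide whether stronger calls are in excess along the whole chromosome. Among peaks 601 to 1119 the chromosome III share was 15.4% in the combined list, 16% in replicate 1 and 14.8% in replicate 2. Stronger binding on chromosome III stays a hypothesis, as do other differences such as gene content, which could not be tested without an annotation of the build.

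The right end of chromosome IV held 1.50 times more replicate 2 peaks than the rest of the genome would give. The longer list of replicate 2 was argued against (1.49 with equal lengths, interval 1.34 to 1.65). So was independent scatter between windows (permutation p = 0.0001, the smallest that 10000 shuffles can give). Outside the central part of the other autosomes replicate 2 also had more peaks, 4789 against 4001. That ratio was 1.20, against 1.09 everywhere outside the region. A general gain at autosome ends may therefore be part of the pattern. It was argued against as the whole cause (1.37 against the ends of the other autosomes, interval 1.23 to 1.52). Extra copies of the region in replicate 2 stay open: the test planned for them, on the ranks of 29 combined peaks, met its bound for excluding them (difference of median log2 rank ratios −0.35, bootstrap interval −1.10 to −0.016, permutation p = 0.28), as did 30 shared peaks of high joint rank (−0.416, interval −0.856 to −0.0396), but such peaks are the strongest of the region alone, and over all 276 shared peaks there the interval reached above 0 (0.023, interval −0.092 to 0.25). By rank, the ratio was 1.04 (interval 0.602 to 1.79) among peaks 1 to 1000, 1.91 (1.48 to 2.46) among peaks 1001 to 4000, 1.49 (1.26 to 1.76) among peaks 4001 to 10000 and 1.39 (1.18 to 1.63) among the peaks after them.

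Both libraries belong to one group, so no biological explanation of the ratio of 1.37 was tested. This arm is known for a broad cluster of piRNA genes. Whether the extra peaks fall on them may be worth checking with an annotation of this build.

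The lowest-ranked replicate peaks, whose scores were near 0, still overlapped between libraries more than chance gave. Broad regions rich in peaks were argued against as the whole cause, because the overlap was at least 1.76 times that under shifts of only 5 to 50 kb, and no such shift reached it (permutation p = 0.001, one-sided). Weak binding and sites that any library enriches, such as open chromatin, could both give this, and they were not separated here because the inputs were not analysed.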
